A study of Homo sapiens and Mus musculus with 33 samples.

How the data were processed

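Gene-level RNA-seq libraries, 21 of cultured human endothelial cells and 12 of mouse brain, were placed in 11 groups of 3 by label. Per the labels' protocols, HUVEC and HREC for the ligand experiments were detached with trypsin and plated on Fc or DLL4 for 6 h. In the EGTA experiment EGTA acted on HREC for 15 min, and after a wash in PBS the cells stood in serum-containing growth medium for 75 min, with or without CpE. The same protocols place CpE on the cells overnight before either EGTA treatment, with a change to fresh medium in the morning. The handling of the EGTA control cells, whose column is marked 0 h, is not given in the sources used here, so removal of the inhibitor may or may not be part of the change after EGTA, and no control that was washed without EGTA is described. RiboTag mice carried Rpl22 with an HA tag switched on in endothelial cells by a Cdh5-driven, tamoxifen-inducible Cre, and brains were collected on postnatal day 8. Brain EC libraries hold RNA pulled down with anti-HA, and homogenate libraries hold total RNA. Per the labels' protocols and sample titles the mice received DAPT for 6 h, while the series' design text names CpE. RNA was isolated with Qiagen kits and libraries were made by Illumina protocols at Novogene or at Columbia University, per the labels' protocols, and the site of each library is not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, animals or donors, so p-values measure only the spread between these libraries, which may be technical.

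The authors deposited tables of whole-number read counts per gene, with 1 column per library, and these counts were used as deposited. Per the submitters' processing notes, STAR 2.5.0a, SAMtools 1.4.1, featureCounts 1.5.2 and DESeq2 1.18.1 were used with the builds GRCh38 and mm10, and no role or order is given for them. The annotation release, the strand setting and any filter are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes have an uncertain split, and reads of near-identical copies may have been dropped or shared. Each of the 33 libraries was taken from 1 column matched to its label, and 15 further per-sample columns, all with the same values as a used column, were left out. The EGTA with CpE libraries lie in another table than the EGTA and control libraries, as do HUVEC and HREC and the 2 brain fractions. Such tables were joined by gene before fitting, which raw counts allow. The mouse tables hold no mitochondrially encoded gene. Coordinates are those of GENCODE 44 for GRCh38 and GENCODE M21 for GRCm38, matched by symbol.

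Total counts ran from 16.4 to 55.4 M per library. Replicates of a group were compared by a chi-square test over genes, and the statistic per degree of freedom lay between 2.2 and 76.4, so no pair of libraries matched within sampling noise and none was merged. Precision was limited less by depth than by this spread.

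Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, two-sided). Genes passed edgeR's expression filter on the groups of the fit, with its minimum count of 10, and libraries were scaled by TMM. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called below 0.05. Each DLL4 experiment was fitted alone. The 3 EGTA groups shared 1 fit of 9 libraries. The inhibitor effects in brain EC and in homogenate were each fitted on 6 libraries, and the comparison of fractions and its interaction on all 12 brain libraries. The DLL4 interaction used the 12 libraries of both ligand experiments. No fit had a block unless stated. Standard errors are approximate (absolute log2 fold change over the root of F). Overlaps of independent experiments were tested by Fisher's exact test, one-sided, over the genes tested in both. Comparisons sharing libraries were set against 60 simulations of unchanged groups drawn from the real means, dispersions and library sizes.

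The 37 gene lists, 30 for both species and 7 for mouse alone, covered the Notch pathway, guidance receptors, endothelial subtypes and functions, signalling and stress responses, metabolism, proliferation, and markers of other cell types that the samples could hold. Results of 2 of these lists and of some genes are not reported here. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of 1 comparison, and again with an estimated correlation. For each list the called members were counted with p-values adjusted over all genes and adjusted over the list alone. No list that passed had a median, a mean and a test of different sign.

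Genes were named by rule. RND1, HES1, HES4, HEY1, HEY2, HEYL, NRARP and DLL4 were named whatever their test. Up to 10 raised and 10 lowered genes per comparison were added by size of log2 fold change. They had to be called, to have a mean log2 CPM of at least 1, an official symbol, and every library of a group on the same side of every library of the other, which chance alone gives for 10% of genes with 3 against 3. Interactions added up to 5 genes of each sign without the condition on sides. Overlaps added all members up to 15, or else the 15 with the largest smallest change. Up to 4 called members of each list were added, or the 2 most expressed where none was called. Groups, lists, tests of the comparisons, naming rule and alternatives were fixed before the data were examined, except for the exclusion of both HUVEC libraries numbered 2. Some tests of explanations, and those on other splits of the libraries, were chosen later.

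Replicate numbers in the labels were checked for pairing by correlating the deviations of same-numbered libraries from their group means, over 11725 to 13446 genes, and numbers were taken to pair libraries where all 3 correlations exceeded 0.1. They did in HUVEC (0.725 to 0.928), among the EGTA groups (0.67 to 0.898) and between brain EC and homogenate, in controls (0.366 to 0.54) and with the inhibitor (0.157 to 0.585). For those comparisons a fit with the number as a block is reported where it changed a call or moved a count by over 1.5 times. Numbers were nested in the experiment for the DLL4 interaction, and in the treatment for the fits of both fractions.

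Alternatives were DESeq2's size factors in edgeR, no low-count filter, DESeq2 1.42.0, the block, other libraries in the fit, and leaving out each library in turn. Each test was also run on simulated data with the real means and library sizes and 200 changed genes. Of genes changed 2-fold edgeR recovered 49.3% in the HUVEC design (14050 genes run), 100% in HREC (15221), 76.1% for EGTA against control (15175), 76.1% for CpE against EGTA (15180), 68.7% for CpE against control (15163), 97.0% in brain EC (14985), 95.5% in homogenate (14937) and 100% between fractions (15381). For the interactions it recovered 50.7% for DLL4 (15632) and 88.1% for the inhibitor (15369). Between 3.24% and 9.01% of its calls were false, as were 2.9% to 9.9% of those with the block. The simulated libraries were not paired by number, so the block's rate does not carry over to real blocked counts. Of DESeq2's calls 2.26% to 22.6% (HUVEC design) were false. With a list changed 1.5-fold in simulated data, camera at the preset correlation also called others. These were 4 in HREC with DLL4, 2 in brain EC, 1 in homogenate, 1 between fractions and none elsewhere. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.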

Results

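RNA-seq read counts per gene were examined in 33 libraries, 21 from cultured human endothelial cells and 12 from mouse brain, in 11 groups of 3. Human umbilical vein endothelial cells (HUVEC) and human retinal microvascular endothelial cells (HREC), both primary cultures, had been seeded for 6 h on plates coated with Fc, the control, or with DLL4, a transmembrane ligand of the Notch receptors. A further HREC experiment compared controls with cells exposed to EGTA for 15 min, washed and kept in medium for 75 min, without or with CpE. Both EGTA groups had CpE overnight before. EGTA chelates calcium, which holds the Notch ectodomain in place, and CpE inhibits gamma-secretase, the protease that releases the Notch intracellular domain. RiboTag mice carried an HA tag on the ribosomes of their endothelial cells. Their brains were taken on postnatal day 8, 6 h after a gamma-secretase inhibitor or in a control state, as total RNA (homogenate) and as RNA precipitated with the tagged ribosomes (brain EC). The labels name DAPT for the mice and the series' design text CpE, so it is called the inhibitor here.

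Total counts, in M for mega, were 23.4, 55.4 and 18.2 M in the HUVEC Fc libraries numbered 1 to 3 and 20.3, 51.1 and 16.4 M in those on DLL4. They were 36.0, 34.9 and 28.9 M in HREC on Fc, and 30.5, 35.2 and 28.7 M in HREC on DLL4. The EGTA experiment held 26.0, 29.1 and 22.1 M in controls, 20.02, 24.0 and 24.2 M after EGTA, and 24.9, 25.1 and 21.9 M after EGTA with CpE. Homogenates held 32.3, 20.8 and 21.1 M in controls and 18.6, 21.2 and 21.6 M with the inhibitor. Brain EC libraries held 24.85, 23.7 and 25.9 M in controls and 27.1, 29.2 and 24.99 M with the inhibitor. The HUVEC libraries numbered 2 stood apart by their depth and by a mitochondrial share of 2.18% and 2.03% of counts, against 1.22% to 1.37% in the other HUVEC libraries. RND1, the small GTPase named in the study's title (ENSG00000172602.11), lies on chromosome 12 of GRCh38 from 48857145 to 48865870 on the minus strand. Its mouse counterpart Rnd1 lies on chromosome 15 of GRCm38 from 98663421 to 98677461, also on the minus strand. Values below are counts over whole genes, in counts per M (CPM), scaled within each fit, as mean ± SD with n = 3 libraries per group, or log2 fold changes (log2FC) ± SE with edgeR's adjusted p.

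Which transcripts respond to immobilised DLL4 was asked in HUVEC. HES1, a transcriptional repressor downstream of Notch, rose from 15.8 ± 5.93 to 66.7 ± 5.82 CPM (log2FC 2.07 ± 0.26, adjusted p = 0.0472). NRARP, a feedback inhibitor of Notch signalling, rose from 23.5 ± 0.949 to 72.9 ± 5.02 CPM (log2FC 1.63 ± 0.096, adjusted p = 0.00906). CD274, an immune checkpoint ligand, fell by 2.21 ± 0.17 on the log2 scale (adjusted p = 0.0114) and CCND1, a cyclin of the G1 phase, by 1.11 ± 0.092 (adjusted p = 0.0114). In all, 29 of 14265 genes changed, 18 raised and 11 lowered, of which 14 and 7 moved at least 2-fold. RND1 averaged 22.3 ± 12.1 CPM on DLL4 and 0.969 ± 0.701 on Fc, higher in each DLL4 library than in any Fc library, and did not pass (log2FC 4.40 ± 0.62, adjusted p = 0.0614). DLL4 (log2FC 2.56, adjusted p = 0.0741), HEY1 (1.55, 0.148), HEY2 (3.17, 0.284), HES4 (1.395, 0.514) and HEYL (1.04, 1) did not pass either.

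Other raised genes in HUVEC were SLC46A3, a lysosomal transporter (log2FC 2.94), SLC45A4, a membrane transporter (2.69), ROR1, a receptor tyrosine kinase-like receptor (2.32), SAT1, an enzyme of polyamine breakdown (2.17), SERPINB9, an inhibitor of granzyme B (1.77), RAPGEF5, an exchange factor for Rap GTPases (1.63), and IER3, an early response gene (1.21). Lowered with CD274 and CCND1 were FST, which encodes the activin antagonist follistatin (log2FC -2.66), the kinases SGK1 (-1.39) and PIM3 (-1.08), SH3TC1 (-1.10), PLAT, the tissue plasminogen activator (-1.06), FOSL2, a subunit of AP-1 (-0.99), the ephrin receptor EPHA4 (-0.97) and RGS2 (-0.96). Of the 11 Notch effectors measured, 2 rose, 5 when adjusted over the list alone, and the list median was 1.04 (camera adjusted p = 7.5e-19, 0.0183 with an estimated correlation). Of 35 immediate early genes IER3 rose and FOSL2 and SGK1 fell, 2 raised and 12 lowered when adjusted over the list alone, with a median of -0.35 (adjusted p = 1.21e-12, and adjusted p = 0.0446 with an estimated correlation). None of 22 arterial genes passed, 6 were raised when adjusted over the list alone, and the median was 0.39 (adjusted p = 1.27e-09, lost at adjusted p = 0.463 with an estimated correlation). ID3, an inhibitor of DNA binding induced by BMP, was the member that rose among 23 BMP and TGF-beta genes (log2FC 0.79), 3 when adjusted over the list alone, with adjusted p = 0.00429 for the list and adjusted p = 0.41 with an estimated correlation. Dissociation stress genes had no member past the test, 3 lowered when adjusted over the list alone, and adjusted p = 3.64e-05 (adjusted p = 0.463 with an estimated correlation).

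HUVEC libraries of the same number deviated together, and with the number as a block 1798 genes changed, 881 raised and 917 lowered, including all 29. Blocked adjusted p was 3.8e-12 for RND1, 3.84e-10 for DLL4, 6.91e-09 for HEY1, 1.18e-06 for HEY2, 4.28e-06 for HES4 and 0.0489 for HEYL, and with the block 7 Notch effectors were raised, as were 13 arterial genes beside 2 lowered. With the block and an estimated correlation Notch effectors and immediate early genes no longer passed (adjusted p = 0.137 for each). The block also brought tip cell genes (adjusted p = 0.000471) and proliferation genes (0.0161) past the list test at the preset correlation (adjusted p = 0.336 and adjusted p = 0.437 with an estimated correlation) and ended that of BMP and TGF-beta genes (0.0506). The unblocked count was 4 without Fc library 1, 45 without Fc 2, 19 without DLL4 library 2 and 2 without DLL4 3. It was 0 by edgeR without Fc 3 or without DLL4 1, with 572 and 616 genes at an unadjusted p below 0.05, and DESeq2 was not run without these libraries. HES1 lost its call without any library but Fc 2 (adjusted p = 0.0771 to 0.268), NRARP lost it without Fc 3 (0.0545) or DLL4 1 (0.116), and none of the 27 named genes past the test kept its call in every such fit. RND1 passed without Fc 2 (adjusted p = 0.0439). The count was 227 with DESeq2, 155 with no low-count filter, and 151 without both libraries numbered 2, an exclusion chosen after the data were seen that kept all 29 genes.

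The same question in HREC gave larger counts. RND1 rose from 5.05 ± 0.301 to 110 ± 4.37 CPM (log2FC 4.45 ± 0.057, adjusted p = 3.67e-33). HEY2, a repressor linked to arterial fate, rose by 3.504 ± 0.13, DLL4 by 2.20 ± 0.036, HEY1 by 1.61 ± 0.078, NRARP by 1.55 ± 0.033, HES4 by 1.52 ± 0.043, HEYL by 1.29 ± 0.26 and HES1 by 0.81 ± 0.040 on the log2 scale, with adjusted p between 9.11e-31 and 0.000202. HES4 overlaps the annotated gene RP11-54O7.17, so the split of reads between them is uncertain. Of 15436 genes tested, 2277 rose and 2093 fell, 269 and 136 of them by at least 2-fold. For the core genes and those named next, all 3 DLL4 libraries lay on the same side of all 3 Fc libraries. AFAP1L2 (log2FC 4.21), the leukocyte adhesion molecules VCAM1 (3.65) and SELE (3.36), SLC45A4 (3.51), CYP1B1, a cytochrome P450 (3.19), and ROR1 (2.66) were among the raised genes. LHX6, a homeobox gene (-3.12), FST (-2.59), CD274 (-2.49), APLN, which encodes the peptide apelin (-2.30), and PLAT (-1.98) were among the lowered ones.

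Gene groups in HREC on DLL4 moved in both directions. Of 11 Notch effectors 7 rose and 2 fell (camera adjusted p = 3.28e-16), and of 23 arterial genes 14 rose and 4 fell (2.72e-29), led by the gap junction gene GJA5 (log2FC 5.02), TMEM100 (4.33), HEY2 and the ligand EFNB2 (2.65). Of 26 NF-kB and inflammatory genes 18 rose and 5 fell (2.94e-11), with the chemokines CX3CL1 (3.84) and CCL2 (2.05) beside VCAM1 and SELE. Of 19 tip cell genes 5 rose, UNC5B (1.82) and KCNE3 (1.23) among them, and 9 fell, with APLN and ADM (-1.71), for adjusted p = 6.91e-08. Of 38 immediate early genes 4 rose and 21 fell (1.57e-12), including SGK1 (-1.80) and EGR1 (-1.62). These 5 list results held with an estimated correlation (adjusted p between 0.0171 and 0.0343). Adjusted over the list alone the counts raised and lowered were 7 and 2, 14 and 4, 18 and 5, 5 and 10, and 4 and 22.

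Other lists passed with the preset correlation alone. Unfolded protein and integrated stress response genes had 1 raised and 11 lowered of 22, 1 and 15 adjusted over the list alone, among them ATF4 (log2FC -0.68) and CHAC1 (-0.97), with adjusted p = 1.63e-05 (adjusted p = 0.286 with an estimated correlation). Dissociation stress genes had 3 raised and 8 lowered of 17, the same counts adjusted over the list alone, with JUN at -0.98 (adjusted p = 0.000171, and 0.183 as the adjusted p with an estimated correlation). Venous genes had 5 raised and 2 lowered of 10, likewise adjusted over the list alone (adjusted p = 0.00306, and adjusted p = 0.219 with an estimated correlation). Proliferation genes had 2 raised and 12 lowered of 34, 13 lowered when adjusted over the list alone, with CCND1 at -1.18 (adjusted p = 0.014, and adjusted p = 0.146 with an estimated correlation). Ribosomal protein genes had 17 lowered of 36, 24 adjusted over the list alone, with a median of -0.069 (adjusted p = 0.0347, and adjusted p = 0.796 with an estimated correlation).

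The remaining lists in HREC did not pass as lists (camera adjusted p from 0.0571 to 0.94), and members moved both ways. In the Notch pathway components JAG1 (1.02) and NOTCH3 (1.21) rose and LFNG, a glycosyltransferase that modifies Notch, fell by 1.84 on the log2 scale, 11 raised and 8 lowered of 32, or 11 and 9 adjusted over the list alone. RND3, a relative of RND1, fell (-0.61). Raised and lowered members were 13 and 6 of 27 semaphorins, plexins and neuropilins (14 and 7 adjusted over the list alone), with SEMA5B at 2.53, 6 and 8 of 22 VEGF signalling genes (6 and 11), with FLT1 at 1.43 and SPRY2 at -1.4, and 8 and 6 of 22 BMP and TGF-beta genes (8 and 7), with SMAD7 at 1.70. They were 8 and 2 of 25 interferon genes (12 and 2 adjusted over the list alone), 5 and 2 of 14 heat shock genes (5 and 2), 5 and 6 of 19 cholesterol synthesis genes (5 and 8), 4 and 9 of 20 glycolysis genes (4 and 9), 7 and 11 of 28 junction genes (8 and 11), and 14 and 13 of 33 integrin and matrix genes (14 and 13). They were 5 and 12 of 25 pan-endothelial markers (6 and 14 adjusted over the list alone), 3 and 2 of 9 Wnt/beta-catenin targets (4 and 2), 2 and 2 of 5 lymphatic markers (2 and 2), 2 and 2 of 10 mural markers (3 and 3), with PDGFRB at 2.24, 1 and 1 of 9 fibroblast markers (1 and 1), 1 and 2 of 6 epithelial markers (1 and 2), and 6 and 0 of 13 mitochondrially encoded genes (8 and 0). CD14 was the lone blood cell marker tested (log2FC 0.076, adjusted p = 0.894). Median and mean differed in sign for junction genes (-0.014 and 0.15, test upward), glycolysis (-0.065 and 0.003, downward), Wnt targets (0.016 and -0.024, upward) and lymphatic markers (0.081 and -0.014, downward). Of 158 named genes past the test 147 kept their call in every fit without 1 library.

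**Figure D1:**
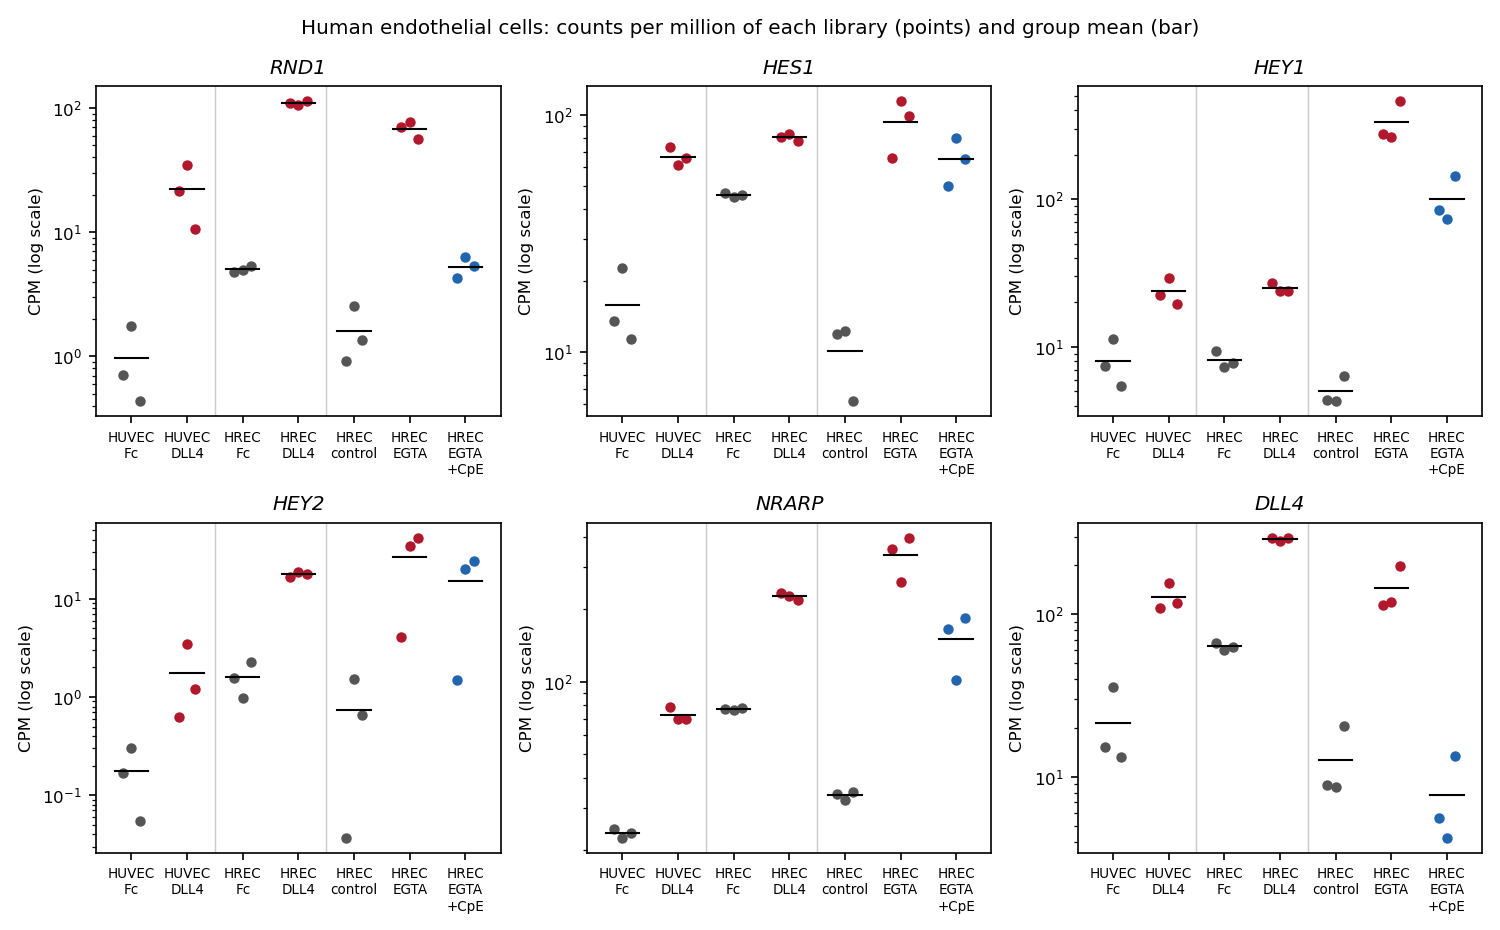
CPM on a log axis in each human library for RND1, HES1, HEY1, HEY2, NRARP and DLL4, with a bar at the mean of each group of 3. RND1 means were 0.969 and 22.3 CPM in HUVEC on Fc and DLL4, 5.05 and 110 in HREC, and 1.61, 67.7 and 5.30 in control, EGTA and EGTA with CpE.

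Genes that passed in both cell sources were then counted. All 18 genes raised in HUVEC were raised in HREC, against 2.82 for independent lists (Fisher's exact test, one-sided, p = 3.08e-15), and all 11 lowered genes were lowered in HREC, against 1.62 (p = 6.96e-10). RARB, a retinoic acid receptor, KCTD12, TACC2 and FHL3 were in the raised set beside the genes named above. PTGER4 and the 10 lowered genes named in HUVEC made up the lowered set. With the block the counts were 734 raised and 707 lowered. The unblocked counts followed the HUVEC calls, with 0 of each without Fc library 3 or DLL4 library 1, and 0 lowered without DLL4 library 3, all by edgeR. They were 134 and 81 with DESeq2, 104 and 49 with no low-count filter, and 102 and 45 without both HUVEC libraries numbered 2. Without Fc 1 they were 3 and 1, without Fc 2 they were 29 and 16, without DLL4 2 they were 12 and 7, and 2 genes were raised without DLL4 3.

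**Figure D2:**
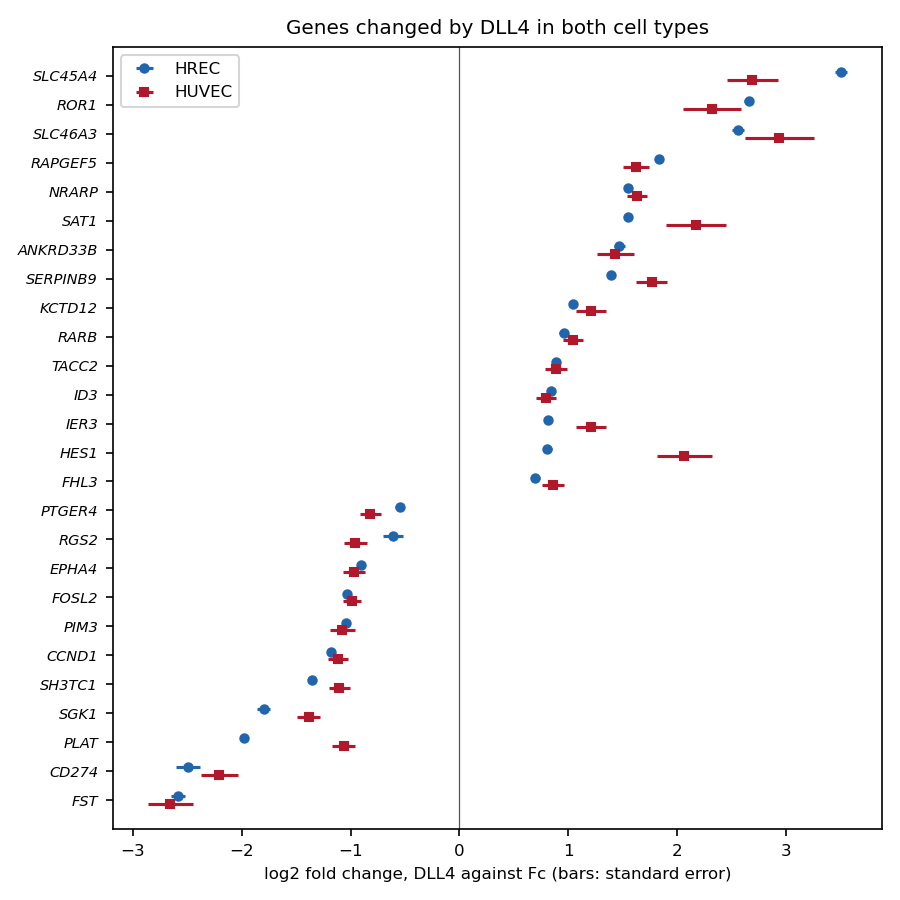
Log2 fold change on DLL4 against Fc in HUVEC and HREC, with SE bars, for named genes that passed in both cell sources. Each gene shown lies on the same side of 0 in both.

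Whether the response to DLL4 differed between HUVEC and HREC was tested as an interaction, and 2 of 16006 genes passed. PLAT fell more in HREC (difference 0.92 ± 0.11, adjusted p = 0.023), and the log2FC of KLHDC8B was lower in HUVEC than in HREC (-0.86 ± 0.093, adjusted p = 0.0184). RND1 differed by -0.12 ± 0.61 and HES1 by 1.26 ± 0.26, neither past the test (adjusted p = 1 and 0.39). NF-kB and inflammatory genes had a median difference of -0.44 (camera adjusted p = 2.07e-13, 0.00886 with an estimated correlation) and unfolded protein and integrated stress genes one of 0.32 (3.94e-15, 0.0254 with an estimated correlation), with no single member past the test, against 3 lowered and 3 raised, in that order, when adjusted over the list alone. With the number as a block within each cell source 450 genes passed, HES1 with adjusted p = 9.92e-05, and so did the lists of Notch effectors, venous genes and BMP genes (0.0328 each), tip cell genes (0.00516) and mitochondrially encoded genes (0.00391). With the block and an estimated correlation none of these 5 passed (adjusted p = 0.218 to 0.571). The unblocked count was 0 by edgeR without HUVEC Fc 1 or DLL4 1 and without any 1 HREC library, with 390 to 655 genes at an unadjusted p below 0.05. It was 7 without HUVEC Fc 2, 4 without Fc 3, 9 without DLL4 2, 3 without DLL4 3 and 89 without both libraries numbered 2, and it was 29 with DESeq2 and 6 with no low-count filter. Cell source and experiment coincide, so they cannot be separated.

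Which transcripts change soon after calcium chelation was asked in HREC exposed to EGTA, where removal of the overnight CpE may play a part. HEY1 rose from 5.01 ± 1.17 to 336 ± 111 CPM (log2FC 6.07 ± 0.38, adjusted p = 2.76e-05) and RND1 from 1.61 ± 0.841 to 67.7 ± 10.7 CPM (log2FC 5.37 ± 0.33, adjusted p = 2.76e-05). HEYL (log2FC 5.26), DLL4 (3.51), NRARP (3.32), HES1 (3.20) and HES4 (2.70) rose as well, each higher in all 3 EGTA libraries than in all 3 controls. HEY2 did not pass (log2FC 5.14 ± 1.30, adjusted p = 0.0552). Of 15450 genes 684 rose and 217 fell, 338 and 40 of them by at least 2-fold. Raised genes included the nuclear receptors NR4A3 (9.18), NR4A1 (6.22) and NR4A2 (4.99), EGR3 (9.06) and FOSB (6.07), which encode transcription factors of the early response, the BMP antagonist NOG (6.48) and SMAD7, an inhibitor of TGF-beta signalling (5.35). MYCN (-2.91), ADM, which encodes adrenomedullin (-1.95), and the clock gene NR1D1 (-1.39) were among those that fell.

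Of 39 immediate early genes 29 rose and 1 fell after EGTA (median 1.51, camera adjusted p = 4.19e-123), 33 and 1 adjusted over the list alone, with EGR4 at 9.52. Of 24 BMP and TGF-beta genes 13 rose (median 1.42, 4.85e-52), among them GREM1 (5.53) and ID2 (4.61), against 15 raised and 1 lowered adjusted over the list alone. Of 22 VEGF signalling genes 8 rose, with DUSP5 (3.47) and SPRY4 (3.12), and 1 fell (1.22e-34), 10 and 1 adjusted over the list alone. Of 12 Notch effectors 8 rose (median 2.90, 1.01e-33), 9 adjusted over the list alone, and of 17 dissociation stress genes 9 rose, ATF3 (3.28) and EGR1 (2.36) among them, and 1 fell (2.22e-43), 10 and 1 adjusted over the list alone. These 5 lists passed with an estimated correlation too (adjusted p between 2.71e-05 and 0.00188). Of 27 NF-kB genes 8 rose, 14 adjusted over the list alone, with CSF2 (5.27), SELE (3.48) and PTGS2 (3.39), and of 20 arterial genes 5 rose and 1 fell, 8 and 2 adjusted over the list alone, with UNC5B (3.04) and EFNB2 (2.28). Both passed with the preset correlation (2.34e-08 and 3.78e-07), and for each of them adjusted p = 0.0933 with an estimated correlation. Unfolded protein and integrated stress genes had 4 raised of 22, 6 adjusted over the list alone, with CEBPB at 1.50 (0.000205, and adjusted p = 0.134 with an estimated correlation). No proliferation gene of 34 passed by either adjustment (list adjusted p = 0.0452, and adjusted p = 0.961 with an estimated correlation).

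EGTA libraries of the same number deviated together with their controls, and with the block 3524 genes changed, 2063 raised and 1461 lowered, including all 901, and HEY2 passed (adjusted p = 1.12e-11). HEY2 also passed without EGTA library 1 (0.0314), with DESeq2 (0.00281) and with no low-count filter (0.00432). The block also brought the lists of Notch pathway components (0.0223), heat shock genes (0.0226) and cholesterol synthesis (0.00582) past the test at the preset correlation (adjusted p = 0.279, 0.73 and 0.0887 with an estimated correlation). With the block arterial genes (adjusted p = 0.00784) and unfolded protein and integrated stress genes (0.0264) passed with an estimated correlation too. Without control library 3 the unblocked count was 529 and without EGTA library 3 it was 539, and 67 of 79 named genes past the test kept their call in every fit without 1 library.

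**Figure D3:**
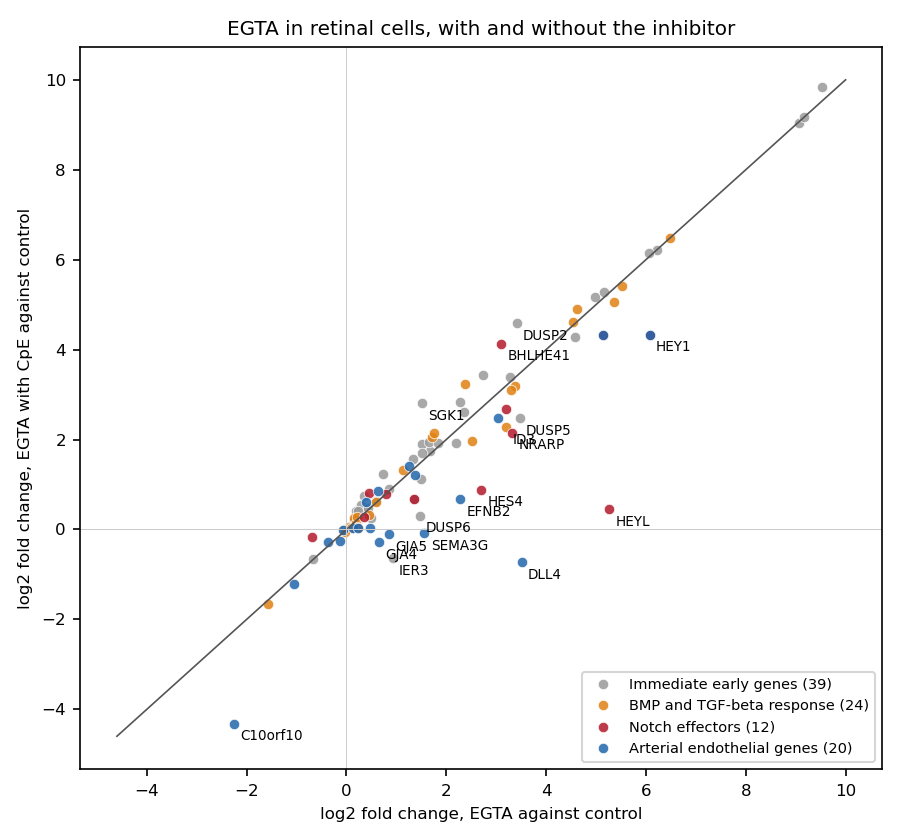
Log2 fold change of EGTA against control (horizontal axis) and of EGTA with CpE against control (vertical axis) in HREC for members of the immediate early, BMP and TGF-beta, Notch effector and arterial lists, with a line of equal values. A gene in more than 1 list has the colour of the list drawn last. HEYL and DLL4 lie far from the line, at 5.26 and 3.51 with EGTA and 0.46 and -0.73 with CpE added.

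Which of these changes depend on gamma-secretase was asked by adding CpE. RND1 fell from 67.7 ± 10.7 to 5.30 ± 1.02 CPM (log2FC -3.68 ± 0.30, adjusted p = 0.0043), HEYL from 6.05 ± 2.53 to 0.215 ± 0.0917 CPM (-4.80 ± 0.47, 0.00571), DLL4 from 144 ± 47.7 to 7.74 ± 4.93 CPM (-4.23 ± 0.52, 0.0175) and HES4 from 59.0 ± 3.87 to 16.8 ± 2.17 CPM (-1.81 ± 0.18, 0.00607), each lower in all 3 CpE libraries. HEY1 (-1.74, adjusted p = 0.115), NRARP (-1.16, 0.172), HEY2 (-0.82, 1) and HES1 (-0.52, 1) did not pass. In all, 3 genes rose and 25 fell. SLC46A3 (-2.02), the ephrin ligands EFNA1 (-1.87) and EFNB2 (-1.62), IER3 (-1.57), DUSP6, a phosphatase of ERK (-1.16), and SERPINB9 (-1.04) were among those that fell. MYCN (2.26), SPRY2, an inhibitor of receptor tyrosine kinase signalling (0.89), and PDE4B, a cyclic AMP phosphodiesterase (0.88), were those that rose. Of 12 Notch effectors HES4, HEYL and MYC (-0.68) fell, 5 adjusted over the list alone (camera adjusted p = 8.56e-22, 0.0139 with an estimated correlation), and of 20 arterial genes DLL4 and EFNB2 fell, 5 adjusted over the list alone (5.35e-17, 0.0375 with an estimated correlation). Of 39 immediate early genes DUSP6, IER3 and MYC fell, against 3 raised and 6 lowered adjusted over the list alone, and of 24 BMP and TGF-beta genes ID3 fell (-0.92), also 1 adjusted over the list alone. Neither list passed (0.852 and 0.467). Ribosomal protein genes (median -0.11, 1.06e-05) and mitochondrially encoded genes (median -0.17, 0.0141) had no member past the test by either adjustment and adjusted p = 0.95 with an estimated correlation.

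With the block 401 genes changed, 165 raised and 236 lowered, including all 28, and HEY1 (adjusted p = 2.35e-12), NRARP (2.61e-07), HEY2 (0.000979) and HES1 (0.048) passed. The unblocked count was 18, 15 and 14 without EGTA library 1, 2 or 3 and 16, 12 and 15 without CpE library 1, 2 or 3, and it was 84 with DESeq2, 50 with no low-count filter and 18 with the controls left out of the fit. DLL4 lost its call without EGTA 2 (adjusted p = 0.0574), EGTA 3 (0.0697), CpE 1 (0.0984) or CpE 2 (0.102), and HEYL without CpE 2 (0.0502), and 9 of 21 named genes past the test kept their call in every fit without 1 library.

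What EGTA did with CpE present was asked by comparing those libraries with the controls. HEY1 rose by 4.33 ± 0.35, HES1 by 2.68 ± 0.31, NRARP by 2.16 ± 0.23, RND1 by 1.70 ± 0.32 and HES4 by 0.89 ± 0.18 on the log2 scale, with adjusted p between 0.000138 and 0.0218. DLL4 (-0.73, adjusted p = 0.537), HEY2 (4.32, 0.0916) and HEYL (0.46, 0.816) did not pass. Of 15450 genes 762 rose and 231 fell, 333 and 36 of them by at least 2-fold. NR4A3 (9.18), EGR3 (9.03), NOG (6.48), NR4A1 (6.21), FOSB (6.16), NR4A2 (5.17) and SMAD7 (5.05) were among the raised genes. C10orf10 (-4.32), GIMAP7 (-1.79), GIMAP1 (-1.48) and GIMAP8 (-1.44) were among those that fell. Of 39 immediate early genes 28 rose and 1 fell (median 1.75, camera adjusted p = 1.14e-119), of 24 BMP and TGF-beta genes 13 rose (1.06e-47), of 22 VEGF signalling genes 9 rose (7.4e-35), of 17 dissociation stress genes 10 rose and 1 fell (3.95e-46), and of 12 Notch effectors 7 rose (1.21e-15). Adjusted over the list alone these were 34 and 2, 15 and 1, 10 and 2, 12 and 1, and 8 and 0, and the lists passed with an estimated correlation (adjusted p between 3.25e-05 and 0.00843). Of 27 NF-kB genes 7 rose, 12 adjusted over the list alone, with PTGS2 at 4.38, and of 22 unfolded protein and integrated stress genes 5 rose, 6 adjusted over the list alone (8.24e-07 and 0.000151, and for both adjusted p = 0.158 with an estimated correlation).

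With the block 3815 genes changed against control, 2134 raised and 1681 lowered, including all 993, and so did DLL4 (-0.73, adjusted p = 0.000796) and HEY2 (2.49e-10). The arterial (6.62e-05), heat shock (0.0123), cholesterol synthesis (0.00105) and mitochondrially encoded (0.04) lists passed with it at the preset correlation (adjusted p = 0.0598, 0.684, 0.0598 and 0.712 with an estimated correlation), and unfolded protein and integrated stress genes then passed with an estimated correlation too (adjusted p = 0.0288). The unblocked count was 602 without control library 3 and 618 without CpE library 3. RND1 lost its call without control 3 (adjusted p = 0.0666), without CpE 2 (0.0503) or with the EGTA group left out of the fit (0.0569), and HES4 without control 3 (0.0719), CpE 1 (0.0635) or CpE 2 (0.0702) or with that group left out (0.0738). Of 56 named genes past the test 43 kept their call in every fit without 1 library.

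All 25 genes that CpE lowered were among those that EGTA raised, against 1.11 for independent lists. It was 0 in each of 60 simulations of unchanged groups that share the EGTA libraries, but these called at most 2 genes per comparison, so a count near 0 was bound to follow. By the rule for shared genes RND1, HEYL, DLL4, SLC46A3, HES4, C2CD4B, EFNB2, EFNA1, DUSP6, SERPINB9, PRAG1, C15orf39, IER3, ID3 and PELO are named. MYCN and PDE4B were lowered by EGTA and raised by CpE, against 0.0421 for independent lists. Of the 25, 24 were also raised by DLL4 in HREC, against 3.73 (Fisher's exact test, one-sided, p = 2.84e-19), and 6 in HUVEC, against 0.0306 (p = 2.19e-13). Those 6, raised by DLL4 in both cell sources and by EGTA and lowered by CpE, were ID3, IER3, RAPGEF5, RP11-54O7.17, SERPINB9 and SLC46A3. With the block the counts were 192, 35 and 122 for the 25, the 2 and the 6. Without EGTA library 1, 2 or 3 the count of 25 was 16, 13 and 12, and without CpE library 1, 2 or 3 it was 14, 10 and 13, and the count of 2 was 1 without EGTA 2 or EGTA 3. The count of 6 was 2 without HUVEC Fc 1, 2 without CpE 2, and 0 by edgeR without HUVEC Fc 3, DLL4 1 or DLL4 3. With DESeq2 the 3 counts were 54, 4 and 21, with no low-count filter the first and the third were 40 and 20, and without both HUVEC libraries numbered 2 the third was 15.

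Of the 684 genes raised by EGTA 560 were also raised with CpE, against 33.7 for independent lists, and of the 217 lowered genes 143 were also lowered, against 3.24, values that leave out the sharing of the 3 control libraries. The log2FC of EGTA and of EGTA with CpE against the same controls correlated at r = 0.865 across genes, which are not independent replicates, against a simulated 0.492, and their covariance was 0.263 against 0.0542. Between EGTA against control and CpE against EGTA r was -0.26, against a simulated -0.505, and the covariance was -0.041 against -0.056, so sharing libraries alone gave the more negative values. The simulated libraries were drawn independently, without the pairing by number that the real ones show, so the simulated values are a rough guide. The 3 shared libraries cannot be split into parts of at least 2, so part of the values may come from sharing them.

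Whether the precipitated RNA was enriched in endothelial transcripts was asked in control mice. All 25 pan-endothelial markers were higher in brain EC than in homogenate (median log2FC 5.27, camera adjusted p = 3.23e-46), as were all 27 blood-brain barrier genes (median 4.18, 5.61e-56), by either adjustment. The tight junction gene Cldn5 went from 58.0 ± 4.52 to 3224 ± 194 CPM (log2FC 5.80 ± 0.088, adjusted p = 1.87e-15). Dll4 (5.04), Hes1 (2.82), Nrarp (1.39), Hey1 (1.10) and Heyl (0.95) were higher in brain EC, Rnd1 was lower, at 39.9 ± 2.80 against 75.7 ± 2.44 CPM (-0.92 ± 0.068, adjusted p = 1.01e-08), and Hey2 did not pass (0.26, 0.112). In all 6438 of 15568 genes were higher and 6025 lower in brain EC, 3033 and 2568 by at least 2-fold. Pglyrp1 (5.86), Icam2 (5.86), Ly6c1 (5.77) and the transporter Slc38a5 (5.61) were among the higher genes. The matrix gene Tnr (-2.16), Erbb4 (-2.07) and Ptprz1 (-2.04) were among the lower ones. Each of the 150 named genes past the test kept its call in every fit without 1 library.

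Arterial (22 raised of 23), venous (12 raised and 1 lowered of 13), tip cell (19 of 19), junction (26 and 1 of 28), BMP and TGF-beta (18 and 4 of 24), immediate early (28 and 7 of 38) and Wnt target genes (12 and 2 of 14) were higher in brain EC, with the same counts adjusted over the list alone but for 18 and 5 BMP genes. These lists, the pan-endothelial and the barrier genes passed with an estimated correlation (adjusted p between 0.00454 and 0.048). Proliferation genes (32 raised of 34, 3.01e-13), integrins and matrix (27 and 3 of 32, 6.02e-08), VEGF signalling (13 and 8 of 22, 1.16e-05), interferon genes (18 and 1 of 23, 3.67e-05), NF-kB genes (17 and 2 of 19, 9.13e-05), dissociation stress genes (15 of 17, 0.000209), Notch pathway components (25 and 6 of 32, 0.000573) and ribosomal protein genes (28 of 35, 0.0177) passed with the preset value, with the same counts adjusted over the list alone but for 19 and 1 interferon genes. Their adjusted p with an estimated correlation was, in that order, 0.0791, 0.367, 0.0593, 0.387, 0.0677, 0.0598, 0.213 and 0.65. All 18 neuron markers (1.98e-09), 13 of 14 oligodendrocyte lineage markers (0.00172), 12 of 14 astrocyte markers (0.0197), 11 of 13 microglia markers (0.0197) and 18 of 20 cholesterol synthesis genes (4.1e-05) were lower in brain EC, by either adjustment, and these calls ended at adjusted p = 0.0931, 0.272, 0.387, 0.387 and 0.272 with an estimated correlation. Higher than in homogenate were 2 astrocyte markers, Gjb6 (2.91) and Gja1 (1.64), 1 microglia marker, Tmem119 (1.53), and 1 cholesterol gene. Fibroblast markers had 9 higher and 1 lower of 11, by either adjustment, with Dcn at 3.48 (0.11, and adjusted p = 0.000311 with the number as a block, or adjusted p = 0.166 with the block and an estimated correlation), and the block ended the call of ribosomal protein genes (0.0588). With the block and an estimated correlation venous genes no longer passed (adjusted p = 0.0802), and VEGF signalling (0.0236) and NF-kB genes (0.0415) did. Choroid plexus and ependymal markers had 8 lower of 10, with Ttr at -1.78, and neural progenitor genes 2 higher, Nes (3.57) among them, and 10 lower of 14, by either adjustment, and neither list passed (0.173 and 0.805).

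The response to the inhibitor was then examined in brain EC. Hes5, a Notch effector, fell from 9.24 ± 1.30 to 1.67 ± 1.02 CPM (log2FC -2.50 ± 0.32, adjusted p = 0.00542), and Dll4 from 169 ± 16.2 to 76.8 ± 5.82 CPM (-1.14 ± 0.083, 0.000694). Hey1 (-1.03, 0.00317), Nrarp (-0.92, 0.00117), Hes1 (-0.60, 0.00419) and Heyl (-0.58, 0.0454) fell too, and Hey2 did not pass (-0.17, 0.475). Rnd1 fell from 38.3 ± 2.38 to 31.2 ± 2.30 CPM (-0.29 ± 0.075, adjusted p = 0.0478), lower in all 3 inhibitor libraries. These CPM are scaled over the 6 brain EC libraries, and those of the fractions above over all 12. Of 15062 genes 584 rose and 671 fell, 82 and 20 of them by at least 2-fold. The chemokine receptor Cxcr4 (-2.18), the netrin receptor Unc5b (-1.49), and Gja5 (-1.05) were among the lowered genes. All of the most raised named genes are induced by interferons, with Rsad2 (2.53), Ifit1 (2.31), Ifit3 (2.24), Iigp1 (1.93), Oasl2 (1.83) and Ifit2 (1.72) among them. Ifit3 went from 14.4 ± 4.95 to 67.8 ± 13.5 CPM.

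Of 23 interferon genes 21 rose in brain EC with the inhibitor, 22 adjusted over the list alone (median 1.41, camera adjusted p = 5.17e-47, and adjusted p = 0.236 with an estimated correlation). Of 13 Notch effectors 1 rose and 5 fell, 2 and 5 adjusted over the list alone (2.23e-05), and of 23 arterial genes 3 rose and 7 fell, 5 and 8 adjusted over the list alone (3.09e-09), both lost at adjusted p = 0.236 with an estimated correlation. Of 19 tip cell genes Igfbp3 rose (0.82) and 5 fell, 4 and 9 adjusted over the list alone, with Esm1 at -0.71 (2.5e-05). Of 35 ribosomal protein genes 17 fell, 32 adjusted over the list alone (median -0.22, 2.8e-13), and their share of counts was 1.70 ± 0.09% in controls and 1.47 ± 0.05% with the inhibitor. Of 11 fibroblast markers Pdgfra (0.42) and Postn (0.60) rose, 6 adjusted over the list alone (median 0.38, 0.000855), of 15 mural markers 1 rose and 3 fell, with Kcnj8 at -1.86, or 1 and 6 adjusted over the list alone (0.0139), and of 13 microglia markers none passed by either adjustment (median 0.26, 0.0143). VEGF signalling genes had 3 lowered of 22, 1 raised and 5 lowered adjusted over the list alone, with Ets1 at -0.42 (0.0264). The 6 lists from tip cell genes to VEGF signalling had adjusted p = 0.634 with an estimated correlation. Dissociation stress genes had 6 raised of 17, by either adjustment, with Zfp36 at 0.55 (0.00162, and adjusted p = 0.491 with an estimated correlation). NF-kB genes had 5 raised of 18, 6 adjusted over the list alone, with Ptgs2 at 1.32 (0.0344), and cholesterol synthesis 1 lowered of 20, 3 adjusted over the list alone (0.0139), both with adjusted p = 0.663 with an estimated correlation. Glycolysis had 3 lowered of 19, 1 raised and 4 lowered adjusted over the list alone (0.0355, and adjusted p = 0.655 with an estimated correlation). Integrin and matrix genes had 1 raised of 32, Timp3 (0.55), 10 adjusted over the list alone (6.15e-05), and semaphorins, plexins and neuropilins 3 raised, with Sema3c at 0.88, and 1 lowered of 29, 4 and 1 adjusted over the list alone (0.0238), both with adjusted p = 0.709 with an estimated correlation.

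Blood cell markers had a median of 0.28 with Lyz2 raised (0.82), 3 raised and 1 lowered of 7 adjusted over the list alone, and did not pass as a list (0.179), and barrier genes had Abcb1a raised (0.34) and the lipid transporter Mfsd2a lowered (-0.82) of 27, 2 and 5 adjusted over the list alone (0.0855). Neural progenitor genes had 2 raised, Dll1 (0.41) among them, and 2 lowered of 14, by either adjustment (0.661), and ependymal and choroid plexus markers had none past the test of 10 by either adjustment (0.52). The top gene by share of counts was the ribosomal RNA gene Rn45s in each control, at 0.745% to 1.204%, and the prostaglandin synthase gene Ptgds in each inhibitor library, at 0.744% to 0.796%. Without control library 1 the count of changed genes was 399, without inhibitor library 1, 2 or 3 it was 621, 126 and 339, and with all 12 brain libraries in the fit it was 2345. More genes rose than fell without control 1 (215 and 184), control 2 (956 and 543) or inhibitor 3 (192 and 147). Rnd1 lost its call without any library but control 2 (adjusted p = 0.0782 to 0.145), and Heyl without any but control 3 (0.0589 to 0.173). Of 107 named genes past the test 32 kept their call in every fit without 1 library.

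**Figure D4:**
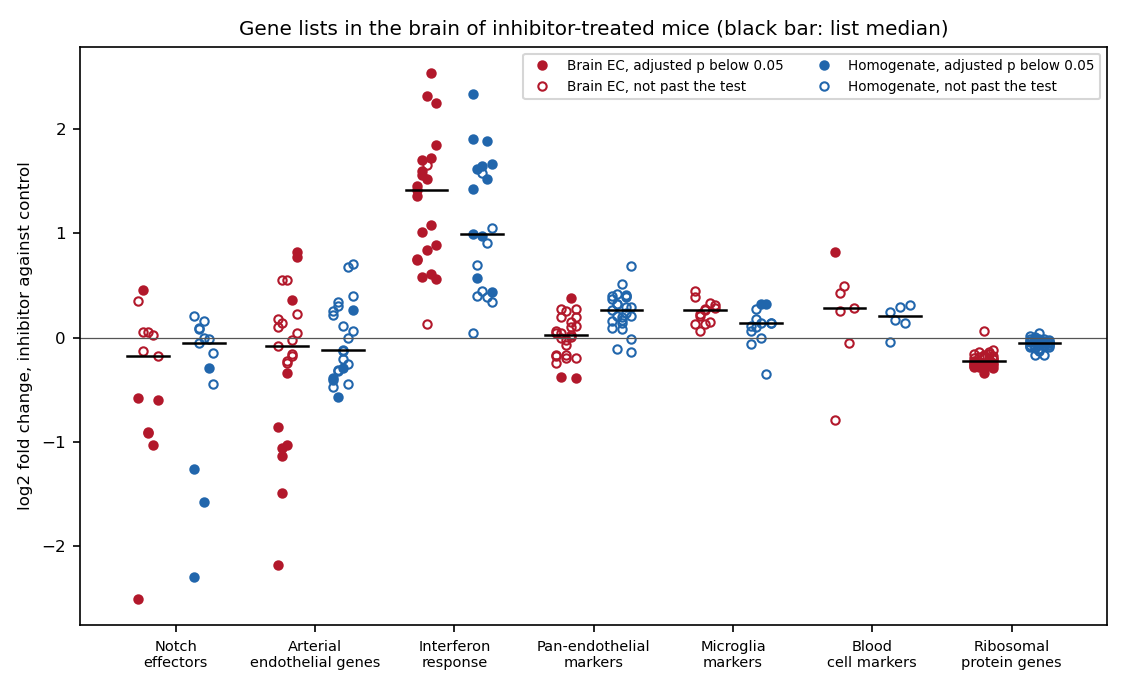
Log2 fold change of inhibitor against control in brain EC and in homogenate for the members of 7 gene lists, filled where the gene passed the test, with a black bar at the list median. The interferon medians are 1.41 in brain EC and 0.99 in homogenate, the highest of the lists drawn.

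The same treatment was examined in whole brain. Nrarp fell from 37.9 ± 1.94 to 12.7 ± 1.10 CPM (log2FC -1.57 ± 0.079, adjusted p = 2.24e-06). Hes5 (-2.29 ± 0.24, adjusted p = 0.00173), Heyl (-1.25 ± 0.14, 0.002) and Hey1 (-0.29 ± 0.062, 0.0348) fell too. Rnd1 (-0.17, adjusted p = 0.111), Dll4 (-0.31, 0.411), Hes1 (-0.15, 0.525) and Hey2 (-0.44, 0.143) did not pass. Of 15019 genes 251 rose and 129 fell, 32 and 10 by at least 2-fold. Irf7 (1.88), Ifit3 (1.64), Oasl2 (1.54), Ly6a (1.178) and Igtp (1.02) were among those that rose. Kcnj8, a potassium channel of pericytes (-2.33), and Unc5b (-0.57) were among those that fell. Of 21 interferon genes 12 rose, 18 adjusted over the list alone (median 0.99, camera adjusted p = 6.41e-25, and adjusted p = 0.211 with an estimated correlation). Of 13 Notch effectors 4 fell, 5 adjusted over the list alone (6.51e-10, and adjusted p = 0.102 with an estimated correlation). Of 15 mural markers 5 fell, 9 adjusted over the list alone, with Higd1b (-1.22), Notch3 (-0.52) and Pdgfrb (-0.49), and of 14 heat shock genes 2 fell, 6 adjusted over the list alone (4.16e-10 and 0.000154, both with adjusted p = 0.162 with an estimated correlation). Cholesterol synthesis had 4 lowered of 20, 13 adjusted over the list alone (3.08e-09), and Wnt targets 1 raised, Apcdd1 (0.42), of 14, 2 raised and 1 lowered adjusted over the list alone (0.0246), both with adjusted p = 0.478 with an estimated correlation. Pan-endothelial markers had no member past the test, 4 raised adjusted over the list alone (median 0.27, 2.31e-05), astrocyte markers 1 raised and 2 lowered of 14, 3 and 5 adjusted over the list alone, with Fabp7 at -0.54 (0.00438), and microglia markers 2 raised of 13, C1qb (0.32) and C1qc (0.33), 3 and 1 adjusted over the list alone (0.0188), each with adjusted p = 0.537 with an estimated correlation. Neuron markers had 2 lowered of 18, 3 adjusted over the list alone (0.00048, and adjusted p = 0.528 with an estimated correlation), and proliferation genes 1 lowered of 34, by either adjustment (0.0026, and adjusted p = 0.355 with an estimated correlation). Barrier genes had 3 raised and 1 lowered of 27, 4 and 3 adjusted over the list alone (0.0238), and ribosomal protein genes none by either adjustment (0.00527), both with adjusted p = 0.699 with an estimated correlation. Oligodendrocyte lineage markers had 2 lowered of 14, Cspg4 (-0.28) among them, 1 raised and 2 lowered adjusted over the list alone, and did not pass (0.697), with a median of 0.016, a mean of -0.017 and a downward test.

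No list call for the inhibitor, in brain EC or homogenate, held with an estimated correlation. The homogenate count was 1319 without control library 1, 94 without control 2, 58 without control 3 (26 raised and 32 lowered) and 38, 33 and 42 without inhibitor library 1, 2 or 3, and it was 687 with no low-count filter and 206 with all 12 libraries in the fit. Of 67 named genes past the test 11 kept their call in every fit without 1 library. Hey1 lost its call without any library but control 1 (adjusted p = 0.0537 to 0.128) and in the fit of 12 (0.14). Brain EC and homogenate shared 93 raised genes, against 9.51 for independent lists, and 38 lowered genes, against 5.81. Same-numbered libraries of the fractions deviated together, so the lists are not independent and no p is given.

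Whether the response differed between the fractions was tested as an interaction, and 69 genes passed, 21 with a higher and 48 with a lower log2FC in brain EC. Cxcr4 had a lower one (difference -1.71 ± 0.17, adjusted p = 0.00159), as did Unc5b (-0.92), Hey1 (-0.74 ± 0.13, 0.0262) and Efnb2 (-0.45). Agtr2 (1.65), Sema3c (0.93 ± 0.12, 0.00509), the adhesion gene Vcam1 (0.93), Timp3 (0.88), Nrarp (0.65 ± 0.12, 0.0252) and Klf6 (0.42) had a higher one. Rnd1 (-0.12, adjusted p = 0.641), Dll4 (-0.82, 0.122), Hes1 (-0.46, 0.138), Heyl (0.68, 0.192) and Hey2 (0.27, 0.645) did not pass. With the number as a block 220 genes passed, including all 69, Dll4 with adjusted p = 0.0131. The unblocked count was 22 and 26 without homogenate control 2 or 3, 36, 24 and 13 without homogenate inhibitor 1, 2 or 3, 45 and 166 without brain EC control 1 or 2, 21 without brain EC inhibitor 2, and 235 with DESeq2. Without brain EC control 2 most of the 166 were higher in brain EC, 107 against 59 lower. Of 18 named genes past the test 4 kept their call in every fit without 1 library. The call of Hey1 ended in 8 such fits (adjusted p = 0.0563 to 0.0868) and that of Nrarp in 7 (0.0541 to 0.102).

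Genes raised by DLL4 in both human cell sources were set against those lowered by the inhibitor in brain EC, with mouse genes matched by symbol. FHL3, HES1, NRARP, SAT1 and SLC45A4 met both, 5 genes against 0.889 for independent lists (Fisher's exact test, one-sided, p = 0.00136, over 10228 genes). With the block the count was 35, of which 4 were among the 5. It was 22 with DESeq2, 19 with no low-count filter, 17 without both HUVEC libraries numbered 2, 9 without HUVEC Fc 2, 1 without HUVEC Fc 1 or DLL4 3, 0 by edgeR without HUVEC Fc 3 or DLL4 1, and 3 without brain EC inhibitor 2 or 3.

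Of the genes raised by DLL4 in HREC 86 were lowered by the inhibitor in brain EC, against 98.3 for independent lists (Fisher's exact test, one-sided, p = 0.929), a difference whose direction changed in another fit, and of the genes lowered by DLL4 176 were lowered by the inhibitor, against 95.6 (p = 9.27e-18, over 10548 genes).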

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

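The tests on microglia and blood markers, on the share of the EGTA rise that CpE removes, on washing and on other splits of the libraries were chosen only after the result was seen, as was the use of the block in HUVEC, itself fixed before, to weigh an explanation.

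By a test of the difference itself, the response to DLL4 differed between HUVEC and HREC for 2 genes. The log2 fold change in HUVEC was lower for KLHDC8B (-0.86) and higher for PLAT (0.92). NF-kB and inflammatory genes had a median difference of -0.44 and unfolded protein and integrated stress genes one of 0.32. That of ribosomal protein genes was 0.083 (camera adjusted p = 0.000494, and adjusted p = 0.875 with an estimated correlation). Of 100 splits drawn, 10 gave at least 2 genes, the real one included, with up to 3924 in another, so chance is not excluded over these splits. All 9 others kept the HREC libraries in their groups or exchanged the groups whole, and so kept the HREC response, and 8 of them mixed the HUVEC libraries. The other, with 1088 genes, exchanged 1 cell source whole and so adds both responses. Counts so far above the real one point to a structure of the samples, here the HREC response, and with the replicate number as a block 450 genes differed.

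The response to the inhibitor differed between brain EC and homogenate for 69 genes. Cxcr4 (-1.71), Zfp69 (-1.49), Chp2 (-1.10), Sigirr (-1.09) and Zap70 (-1.05) had the lower log2 fold change in brain EC, and Agtr2 (1.65), Ifit2 (1.32), Ifi203 (1.07), Sema3c (0.93) and Vcam1 (0.93) the higher one. Median differences were positive for fibroblast markers (0.37), dissociation stress (0.28), interferon (0.26), NF-kB (0.20), integrin and matrix (0.15), immediate early (0.14), unfolded protein (0.12) and semaphorin genes (0.12). They were negative for pan-endothelial (-0.27), tip cell (-0.21), ribosomal protein (-0.17), barrier (-0.17), Wnt target (-0.16) and arterial genes (-0.13). Camera adjusted p lay between 1.34e-09 and 0.0311, and no call held with an estimated correlation (adjusted p = 0.504 to 0.804). Of 100 splits drawn, 6 gave at least 69 genes, the real one included, with up to 149 in another, so chance is not excluded over these splits. Those with more are no clean picture of chance, since they kept the brain EC libraries in their groups and with them the brain EC response, and mixed the homogenate libraries. Splits that kept neither response gave at most 1 gene and those that kept homogenate alone at most 3, and the blocked count was 220.

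Interferon genes rose with the inhibitor in brain EC, with a median log2 fold change of 1.41 over 23 genes (camera adjusted p = 5.17e-47, and adjusted p = 0.236 with an estimated correlation). More microglia or blood cells, which the pull-down should deplete, are argued against as the whole source. Their 19 markers had a median of 0.26 and an upper quartile of 0.36, below the interferon lower quartile of 0.795. Lyz2 passed as raised, as did the microglia list at the preset correlation, and a response within these cells was not tested. No single library carried the rise, as the median stayed between 1.28 and 1.61 in the 6 fits without 1 library. Animals or litters that differed before treatment could give the same pattern and cannot be told apart from treatment, since the lowest inhibitor library lay 0.83 above the highest control in mean log2 CPM of the list in brain EC and 0.48 above it in homogenate, and the labels name no litters. A response of the brain to the inhibitor stays open beside it as a hypothesis.

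Immediate early genes rose after EGTA whether CpE was present or not. Gamma-secretase activity as the source of that rise is argued against, because CpE removed a median of -3.46% of it on the log2 scale over 29 raised genes (quartiles -13.2% and 6.34%), against 31.9% over 8 Notch effectors, and on the linear scale -6.71% (-25.7% and 19%) against 61.7%. Washing and fresh medium could raise these genes and cannot be told apart from EGTA itself, since no washed control is described, and dissociation stress genes had a median of 0.74 in EGTA with CpE against control. Loss of calcium stays open as the biological alternative, untested.

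DLL4 changed 29 genes in HUVEC and 4370 in HREC. Lower depth in HUVEC is argued against, as HREC libraries thinned to the depth of HUVEC libraries still gave 4044 genes. Differences between the same-numbered HUVEC pairs are consistent with the lower count, since the block raised it to 1798. A smaller response in HUVEC may add to it and stays open, with a median ratio of HUVEC to HREC log2 fold changes of 0.723 (95% bootstrap interval over genes 0.669 to 0.77, which leaves out the spread between libraries) over 316 genes chosen for a change of at least 2-fold in HREC, a choice that can lower the ratio. Of these 307 had the same sign in HUVEC (97.2%), and cell source and experiment are not separated in this design.

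For each comparison of 3 libraries with 3 there are 10 splits, too few for a share under 0.05, and in each the real split alone (1 of 10) gave as many genes by edgeR. The highest other count was 1 for the inhibitor in homogenate, against a real 380, and 0 elsewhere. Splits that part as many same-numbered pairs as the real one gave 0 genes in each paired comparison.

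For genes raised by EGTA and lowered by CpE, 4 of 100 splits gave at least the real 25, the real one included, a share under 0.05, with a highest other of 750. For the 2 genes lowered by EGTA and raised by CpE it was 5 of 100, with a highest other of 1426, and chance is not excluded. The split with 750 and 1426 put all 3 libraries of each number together, which points to replicate number as a structure of these samples. Of the 8 splits nearest to that, where 7 of the 9 libraries had the commonest number of their group, 1 gave 574 and 1227, 1 gave 12 and 9 and 6 gave 0. Only the 12 splits that put each number once in every group, the real one included, keep the balance of numbers. Of these 2 gave at least 25, so chance is not excluded. The other 1 of the 2 gave 113 and 508 genes and kept the 3 control libraries together in the place of the EGTA group, and the remaining ones gave 0. With the block the counts were 192 and 35. For genes raised (18) or lowered (11) by DLL4 in both cell sources, for the 6 also raised by EGTA and lowered by CpE, and for the 5 also lowered in brain EC, only the real split of 100 gave as many (1 of 100), with 0 as the highest other. No other split of HUVEC or of HREC called a gene, so those zeros were bound to follow and decide nothing on chance.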

How the results depend on the processing

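The exclusion of both HUVEC libraries numbered 2 was chosen only after seeing the data, and the other alternatives were planned. No call of a list or named gene changed its direction. With DESeq2's size factors all 16 counts of genes stayed within 1.5 times, and of the results of named genes 1046 stayed on their side of the threshold and 3 calls were lost. The counts for HREC with DLL4 (4370) and for brain EC against homogenate (12463) stayed within 1.5 times under every alternative, at 3342 to 4359 and 11966 to 12705.

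With no low-count filter, which tests more genes, the count for DLL4 in HUVEC went from 29 to 155, for CpE against EGTA from 28 to 50, for the inhibitor in homogenate from 380 to 687 and for the DLL4 interaction from 2 to 6. Genes raised by EGTA and lowered by CpE went from 25 to 40, genes raised by DLL4 in both cell sources from 18 to 104, lowered ones from 11 to 49, those also raised by EGTA and lowered by CpE from 6 to 20, and those also lowered in brain EC from 5 to 19. DESeq2 called 227, 84, 54, 134, 81, 21 and 22 for HUVEC, CpE against EGTA and these 5 overlaps, 4 in place of 2 for genes lowered by EGTA and raised by CpE, 29 in place of 2 for the DLL4 interaction and 235 in place of 69 for the inhibitor interaction. Without both HUVEC libraries numbered 2 the HUVEC count was 151, the DLL4 interaction 89, and the overlaps that use HUVEC 102, 45, 15 and 17. With only the groups compared in the fit, CpE against EGTA gave 18, with fewer libraries to estimate the spread. With all 12 brain libraries the inhibitor gave 2345 in brain EC and 206 in homogenate. Where no construction is named here the cause was not tested.

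With the replicate number as a block, where the numbers pair the libraries, the counts were 1798 in HUVEC, 3524 for EGTA, 401 for CpE against EGTA, 3815 for EGTA with CpE against control, 450 for the DLL4 interaction and 220 for the inhibitor interaction. The overlaps had 192 and 35 (EGTA and CpE), 734 and 707 (DLL4 raised and lowered), 122 and 35. The block changed no call of a list in a paired comparison other than those given with their comparisons. It gained 127 calls of named genes, all in those comparisons, and lost 73, all in the inhibitor comparisons within a brain fraction, where the numbers do not pair the libraries.

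In 3 comparisons libraries share only a number. Correlations of deviations were -0.053 to 0.027 in HREC with DLL4, -0.205 to 0.05 in brain EC and -0.29 to 0.087 in homogenate, and 1, 1 and 0 of 6 libraries correlated best with their own number. A block there gave 4232, 595 (354 raised, 241 lowered) and 141 genes (110 raised, 31 lowered), of which 4208, 560 and 125 were called without it. Ribosomal protein genes in HREC (adjusted p = 0.0516), glycolysis in brain EC (0.0502), Heyl (0.0723) and Rnd1 (0.09) in brain EC and Hey1 in homogenate (0.0692) were not called with it, and ependymal and choroid plexus markers in homogenate were (0.0354). The 5 lists in HREC that held with an estimated correlation did not hold with it and the block (adjusted p = 0.141 to 0.246). Genes raised by DLL4 in HREC and lowered by the inhibitor in brain EC went from 86, under the 98.3 of independent lists, to 46, over the 33.2 (Fisher's exact test, one-sided, p = 0.0113), so the direction of that difference changed, and genes lowered by both from 176 to 62, against 32.3 (p = 1e-07). Brain EC and homogenate then shared 34 raised and 12 lowered genes, against 2.51 and 0.483.

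Without 1 library, which leaves fewer samples, counts ran from 0 to 45 in HUVEC and 529 to 633 for EGTA. They were 12 to 18 for CpE against EGTA and 602 to 697 for EGTA with CpE against control. They ran from 126 (without inhibitor 2) to 1499 (without control 2) in brain EC and 33 to 1319 in homogenate. For the interactions they ran from 0 to 9 (DLL4) and 13 to 166 (inhibitor). For the overlaps they were 10 to 22 and 1 to 2 (EGTA and CpE), 0 to 29 and 0 to 16 (DLL4), 0 to 9 and 0 to 9. The counts of 0 are by edgeR, with 390 to 655 genes at an unadjusted p under 0.05 in HUVEC and the interaction. DESeq2 was not run without 1 library. Why some fits without 1 library called more genes was not tested. Of these counts 78 stayed within 1.5 times and 75 moved.

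Of the results of named genes, 6232 stayed on their side of the threshold in fits without 1 library, 859 calls were lost and 24 gained. With DESeq2 975 stayed, 15 were lost and 49 gained, and 10 had no adjusted p, and with no filter 1005 stayed, 3 were lost and 41 gained. With only the groups compared 426 stayed and 14 were lost, with all 12 brain libraries 176 stayed, 24 were lost and 1 was gained, and without both HUVEC libraries numbered 2 150 stayed and 25 were gained. Over all alternatives 383 gene and 13 list results changed sign without a call in either fit. With an estimated correlation 242 list results stayed the same and 76 calls were lost, and with the block 298 stayed, 16 were gained and 4 lost.

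Depth limits these results for genes under the minimum count of 10, which were not tested. Above it the spread between libraries limits the calls, since in simulated data of the HUVEC design edgeR recovered 5.97% of genes changed 1.5-fold and 49.3% of those changed 2-fold, against 97.0% and 100% in HREC.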

Other observations

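The test of the genes sensitive to CpE in brain EC was chosen only after the result was seen, and the tests of ribosomal protein genes and gene length were set before their values were seen.

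The share of the EGTA rise, on the log2 scale, that CpE removed in HREC was computed for each gene raised by EGTA. Over the 8 Notch effectors raised by EGTA the median share removed was 31.9% (quartiles 12% and 54.5%), and over the 5 raised arterial genes it was 28.6% (18.2% and 70.8%). Over the 13 raised BMP and TGF-beta genes it was 2.27% (-6.45% and 6.17%), and over the 29 raised immediate early genes -3.46% (-13.2% and 6.34%). The shares depend on the scale, and of the rise in fold on the linear scale the medians were 61.7%, 71.1%, 8.5% and -6.71% in that order. The difference between the groups was not tested, and the shares rest on the same 3 EGTA libraries.

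Of the genes that EGTA raised and CpE lowered in HREC, 18 were measured in brain EC under the same symbol. A hypothesis is that the same genes depend on gamma-secretase there. With the inhibitor 14 of the 18 had a negative log2 fold change in brain EC (77.8%, against 50.3% of all matched genes, exact binomial test, two-sided, p = 0.0309, median -0.15), which is consistent with it, though genes are not independent replicates. Dll4 (-1.14), Efna1 (-0.97), Heyl (-0.58), Efnb2 (-0.34) and Rnd1 (-0.29) passed as lowered, and Ier3 (0.67) and Zfp36l2 (0.27) as raised. Efna1 and Zfp36l2 were named after their values were seen. Heyl and Rnd1 lost their calls in most fits without 1 library. Of the genes found with the replicate block in culture, 89 of 140 were negative (63.6%, p = 0.00172 by the same exact test). Cell preparation and species differ between the experiments, and the sources used here name different inhibitors for the mice.

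Genes lowered by DLL4 in HREC were also over-represented among those lowered by the inhibitor in brain EC, 2 treatments with opposite aims on Notch, with an odds ratio of 2.34 over 10548 matched genes. The overlap of 176 genes held 18 ribosomal protein genes, and without these the odds ratio was 2.21 (95% interval 1.81 to 2.69). The median exon length was 3854 bases for genes lowered in both and 5664 for all matched genes, and over 10 classes of exon length the common odds ratio was 2.25 (1.86 to 2.72), with a length known for 97.4% of matched genes and 98.9% of the overlap. Neither ribosomal protein genes nor length therefore accounts for the overlap, and other sources were not tested.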
